A study of Mus musculus with 23 samples.

How the data were processed

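RNA of 23 samples from the mouse striatal cell lines Q7 and Q111, untreated or treated for 12 h with ZDON (50 µM), Boc-DON (50 µM) or cystamine (250 µM), had been hybridised to Illumina mouse bead arrays. The deposited non-normalized table holds probe intensity values that the authors summarised with BeadStudio (version not stated) per the submitters' processing notes. Whether a background was subtracted is not given in the sources used here. The deposited series matrix holds log2 values that the authors normalized between arrays by a method not given in the sources used here, and the values equal a quantile normalization of the log2 intensities within 5e-09. The analysis started from the non-normalized intensities. The table had 1 array column with no sample in the labels, which was left out, and Q7 with Boc-DON therefore has 2 arrays. Median signals per array lay between 107 and 165, with no detection p-values and no control probes, so that genes near the background could not be told from absent ones. For arrays, their number limits the precision.

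Intensities were background-corrected with normexp (offset 50), quantile normalized and taken to log2 with limma 3.58.1 in R 4.3.3. Of 24611 probes, 19851 carried 1 gene symbol, 4760 none and 0 several. Probes above the median of their array on at least 2 arrays were kept, 15049 in all and 12504 with a symbol. For each gene the kept probe with the highest mean was used, which left 9849 genes. Probes without a symbol were tested apart from the genes, with the same model.

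All 23 arrays entered 1 limma model with a mean for each of the 8 groups, no covariate and 15 residual degrees of freedom. Its moderated test gave the line difference, each compound against the control of its line, the difference between the lines in the response to each compound, and ZDON against Boc-DON within each line. P-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. The replicate numbers in the sample titles followed the BeadChip in the sample descriptions, so that replicates with 1 number had a chip in common. After group means were removed, the correlation across genes of arrays with the same number had a median of 0.208 (72 of 77 pairs above 0), against −0.111 (44 of 154) for different numbers, where genes are not independent replicates. A model with the replicate number as a fixed block (13 residual degrees of freedom) was therefore run beside the first, and results that it changed are given as blocked values.

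The 40 gene lists covered stress responses, metabolism, proteostasis, cell cycle, signalling, genes tied to huntingtin and TG2, and markers of other cell types. Of these, 37 had at least 5 measured genes and were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The lists that could not be tested were the transglutaminase family (3 of 10 measured, Tgm1, Tgm2 and Tgm4), microglia markers (3) and oligodendrocyte markers (4). In the line comparison Tgm1 stood at 0.07 and Tgm4 at −0.08. Genes named in the text were, for each comparison, the 6 largest upward and the 6 largest downward changes past the threshold whose groups did not overlap, or 4 each way for interactions and for ZDON against Boc-DON. For each list described, up to 4 members with the smallest adjusted p were added, and Tgm2, Htt, Ppargc1a, Cycs and Bdnf were named whatever their values. Genes past the threshold with the block alone were added by the same rule of size after the data had been examined. Outside these rules, Nqo1, Dyrk3, Slc20a2 and Ssbp2, Hmox1 and Mt1 with cystamine, Srxn1 with cystamine in Q111, Ccl7 with Boc-DON in Q7, values of a named gene in further comparisons and genes shared by a pair of comparisons were chosen after their values were seen. So were Dlx2 and Pde10a, which meet the rule for lists. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

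Genes that differ between the lines share the untreated Q111 arrays with every compound effect in Q111. Line genes were therefore taken from the mean difference in the arms of the other compounds, and the share that moved towards Q7 was counted. The sharing itself was measured by 100 simulations with the observed spread, shared controls and no compound effect. A second set of 100, added after seeing the data, held the chip differences as well, as equal in both lines, and was fitted without and with the block. The controls, 3 per line, cannot be divided into separate sets of at least 2.

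The alternatives were the replicate block, no filter, no background correction, median scaling in place of quantile normalization, the deposited log2 values, a model with the arrays of the groups compared alone, and leaving out each array in turn. Leaving out chip 3, the block together with an estimated correlation, and, for the list tests, every setting but the block and the estimated correlation were added after seeing the data. The settings were also run for genes named outside the rules that passed the test. The model was tested on simulated data, where it found 46.3% of changes of 0.5, 92.5% of changes of 1 and 100% of changes of 2 (log2) between the lines, with 2 unchanged genes called. For cystamine in Q111 it found 43.3%, 95.5% and 100%, with 2 unchanged genes called. With the block, 62.7% and 58.2% of changes of 0.5 were found in these comparisons, with 5 and 7 unchanged genes called. Camera found 5 of 5 lists shifted by 0.3 and called 0 of 29 without a shifted member. The simulated noise was independent between genes, so these list results cannot test the preset correlation. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.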

Results

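Messenger RNA was measured on 23 Illumina mouse bead arrays in 2 striatal cell lines, Q111, which was made from a mouse model of Huntington disease, and Q7, its control line. Cells of both lines received ZDON at 50 µM, Boc-DON at 50 µM or cystamine at 250 µM for 12 h, or no compound, and the stated question was the effect of inhibiting transglutaminase 2 (TG2), an enzyme that cross-links proteins through glutamine residues. The untreated samples carry no dose or time in the labels, so whether they got a vehicle for 12 h is unknown. An effect of a vehicle or of time therefore cannot be told apart from that of a compound. Each of the 8 groups held 3 arrays except Q7 with Boc-DON, which held 2 because 1 array had failed the submitters' quality control. The median signal per array lay between 107 and 165 intensity units before normalization. Replicates 1, 2 and 3 of a group sat on BeadChips 1, 2 and 3. Q7 with Boc-DON had no array on chip 3, so its comparisons are balanced over the chips only with the replicate number as a block, which also moves their estimates. Values are log2 differences between group means with their standard error (SE) and the Benjamini-Hochberg adjusted p of limma over 9849 genes. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

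The first principal component held 23.6% of the variance, of which 65.7% lay between the lines and 23.8% between the BeadChips. The lines separated on it within each chip. Across chips they overlapped, as on chip 3 the lowest Q111 array, at −4.38, lay below Q7 ZDON replicate 1 of chip 1, at −3.91. The second held 16.7%, of which 48.3% lay between the BeadChips, and the third held 12.0%, of which 68.9% lay between the treatments.

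**Figure D1:**
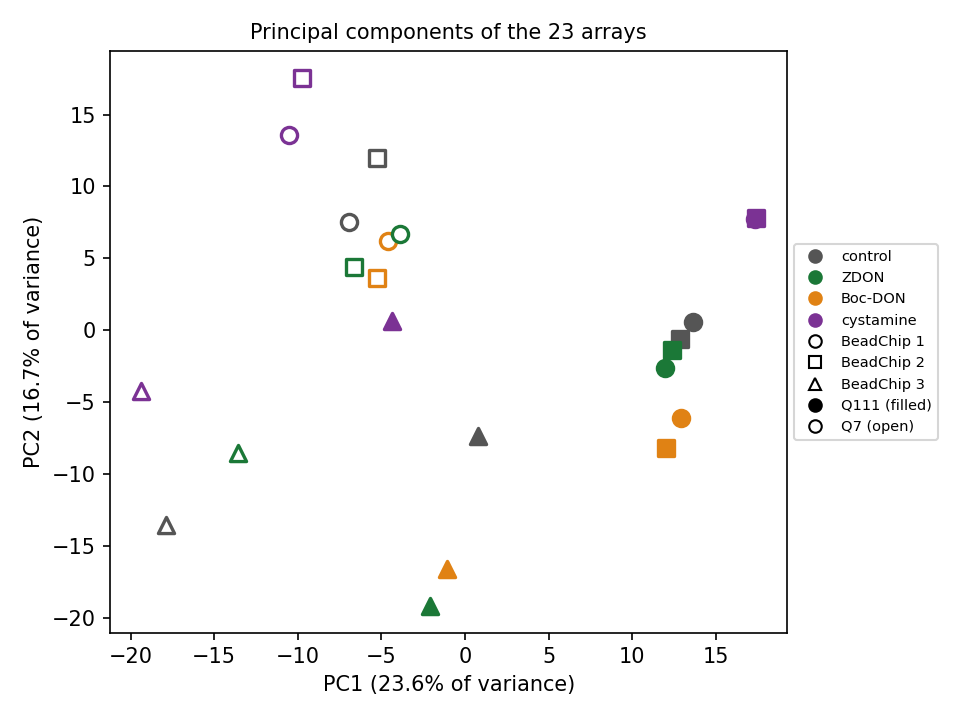
Scores of the 23 arrays on the first principal component (x axis, 23.6% of the variance) and the second (y axis, 16.7%) of the normalized log2 intensities; colour gives the treatment, the shape of a point its BeadChip, and filled points are Q111 and open points Q7. Between the lines lay 65.7% of the first component, and between the chips 48.3% of the second.

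Untreated Q111 and Q7 were compared, a single line each, so disease and other line effects cannot be told apart. Bag3, a co-chaperone that takes part in selective autophagy, was higher in Q111 by a measured 3.72 (SE 0.29, adjusted p = 2.84e-07), with a mean log2 level of 10.05 ± 0.466 in Q111 and 6.328 ± 0.0806 in Q7 (SD, n = 3 each). Thbs2, a secreted matrix glycoprotein, was higher by 2.77 (SE 0.33, adjusted p = 6.2e-05), Medag by 2.49 (SE 0.30, adjusted p = 6.2e-05), the transcription factor Sim2 by 2.47, the membrane glycoprotein Emb by 2.39 and the RNA-binding protein Bicc1 by 2.37. In the other direction Slco4a1, an organic anion transporter, differed by −2.38 (SE 0.48, adjusted p = 0.00903), although a second probe for it gave −0.065. The BMP antagonist Grem1 was lower by 1.93 (SE 0.36), the retinoic acid binding protein Crabp1 by 1.91 (SE 0.41), the G-protein regulators Rgs17 by 1.81 and Rgs16 by 1.40, and the placental hormone Prl2c2 by 1.72 (SE 0.20). Some of these sizes rest on a level near the background. In Q7, Bag3 lay at the 19.8th percentile of the probes on its arrays, Sim2 at the 13th, Emb at the 8.56th and Bicc1 at the 32.8th, and in Q111 Rgs17 lay at the 38.0th, all under the median of each array. Their size and rank depend on the treatment of the background, and with no background correction Bag3 in Q111 control against Q7 control was 3.53. In all, 153 of 9849 genes differed, 104 higher and 49 lower in Q111, and 318 (207 higher) with the replicate block, among them all 153. Genes lower in Q111 were 23 with median scaling (105 higher) and 20 with the arrays of both groups fitted alone (68 higher). En1, a homeobox transcription factor, passed only with the block, at −2.08 (SE 0.63, adjusted p = 0.131 without and 0.00786 with it).

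Genes of the extracellular matrix passed as a list with the preset correlation alone. Of 28 measured genes for collagens and matrix, 5 passed the test over all genes and 9 when adjusted over the list alone, all higher, and the list's median was 0.248 (adjusted p = 1.23e-06, but adjusted p = 0.48 with an estimated correlation). Beside Thbs2 these included Lox, the lysyl oxidase that cross-links collagen, at 2.13 (SE 0.39, adjusted p = 0.00391), Col1a2 at 1.21 (SE 0.23, adjusted p = 0.00613) and Loxl1 at 0.63 (SE 0.13, adjusted p = 0.00878). The 13 fibroblast and mesenchymal markers, which share Lox, Col1a2 and Col1a1 with that list, had 3 higher members over all genes and 4 adjusted over the list alone, with a median of 0.334 (adjusted p = 0.0128, and adjusted p = 0.48 with an estimated correlation). Pdgfra, a growth factor receptor of mesenchymal cells, was higher by 1.29 (SE 0.30, adjusted p = 0.0256), and Col1a1 stood at 1.66 (SE 0.45, adjusted p = 0.0724, blocked 0.0414). Among 14 TGF-beta targets, 2 were higher over all genes and 2 adjusted over the list alone, Tgfbi by 2.31 (SE 0.30, adjusted p = 0.000128) and Tgfb3 by 0.72 (SE 0.17, adjusted p = 0.0339). That list's median was 0.079 (adjusted p = 0.0225, and adjusted p = 0.685 with an estimated correlation).

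Of 17 genes of NF-kappaB and inflammation, 2 were lower in Q111 over all genes, while 1 was higher and 5 lower when adjusted over the list alone. Their median was −0.141 (adjusted p = 0.0232, and adjusted p = 0.313 with an estimated correlation). The chemokine Ccl2 was lower by 1.04 (SE 0.19, adjusted p = 0.00395) and the NF-kappaB inhibitor Nfkbia by 0.61 (SE 0.13, adjusted p = 0.0119). The list of ATF4 targets in the response to amino acid shortage passed only with the block (median 0.0756, adjusted p = 0.0873, blocked 0.0283, and 0.609 blocked with an estimated correlation). Its named members went both ways, with Chac1 higher by 0.60 (adjusted p = 0.0429), Fgf21 higher by 0.56 (adjusted p = 0.0263) and Ddit4 lower by 0.62 (adjusted p = 0.0163).

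Genes chosen beforehand for their link to the disease or to TG2 showed no difference that passed the test. Tgm2, which encodes TG2, stood at −0.05 (SE 0.30, 95% confidence interval −0.668 to 0.56, adjusted p = 0.972), and its value was −0.545 and −0.627 on chips 1 and 2 but 1.01 on chip 3. Htt stood at −0.18 (SE 0.12, adjusted p = 0.653), Ppargc1a, which encodes PGC-1alpha, at −0.21 (SE 0.16, adjusted p = 0.71), cytochrome c (Cycs) at −0.21 (SE 0.15, adjusted p = 0.687) and Bdnf at −0.01 (SE 0.14, adjusted p = 0.984). The medians of the lists were −0.0748 for the PGC-1alpha axis (adjusted p = 0.323), 0.0492 for oxidative phosphorylation (adjusted p = 0.458) and −0.0712 for huntingtin and its partners (adjusted p = 0.344). Markers of cell types gave 0.0339 for striatal projection neurons (adjusted p = 0.727), 0.0621 for neuronal genes (adjusted p = 0.78), −0.0432 for astrocytes (adjusted p = 0.877) and 0.0409 for endothelial cells and pericytes (adjusted p = 0.727). Of the 11 neural progenitor markers (median 0.000331, adjusted p = 0.41) Dlx2 was higher, by 1.55 (SE 0.27, adjusted p = 0.00279). Pde10a, a phosphodiesterase abundant in striatal projection neurons, was lower by 0.82 (SE 0.15, adjusted p = 0.00423).

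The line difference was smaller on chip 3, which neither model allows for, so line p-values may be too small. Across the line genes, the slope of the difference on a chip against that in the other arms was 1.10 on chip 1, 1.07 on chip 2 and 0.677 on chip 3. Bag3 kept a difference of 4.0, 3.89 and 3.27 on the 3 chips, whereas Crabp1 gave −2.52, −2.73 and −0.474 and En1 −3.02, −2.81 and −0.407. Collagens and matrix genes had medians of 0.482, 0.531 and −0.0631, fibroblast markers 0.422, 0.246 and 0.273, TGF-beta targets 0.166, 0.233 and 0.0384, and NF-kappaB genes −0.197, −0.107 and −0.189. Without chip 3 the count of genes was 392. It was 75 without Q7 control replicate 1, 98 without Q7 control replicate 2, 86 without Q111 control replicate 1 and 73 without Q111 control replicate 2. Leaving out 1 control array ended the calls of Col1a2 (adjusted p = 0.0593 without Q111 replicate 2), Slco4a1 (up to 0.0639, without Q7 replicate 1 or 2), Loxl1 (up to 0.0638, without Q7 replicate 1 or 2 or Q111 replicate 2), Nfkbia (up to 0.0916, without Q7 replicate 1 or Q111 replicate 2 or 3), Crabp1 (up to 0.126, without replicate 1 or 2 of either line), Pdgfra (up to 0.152) and Tgfb3 (up to 0.188). The last pair lost the call without any Q7 array and without Q111 replicate 1 or 2, and so did Chac1 (up to 0.212) and Fgf21 (up to 0.206). Ddit4 lost its call without replicate 2 or 3 of either line (up to 0.0787).

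**Figure D2:**
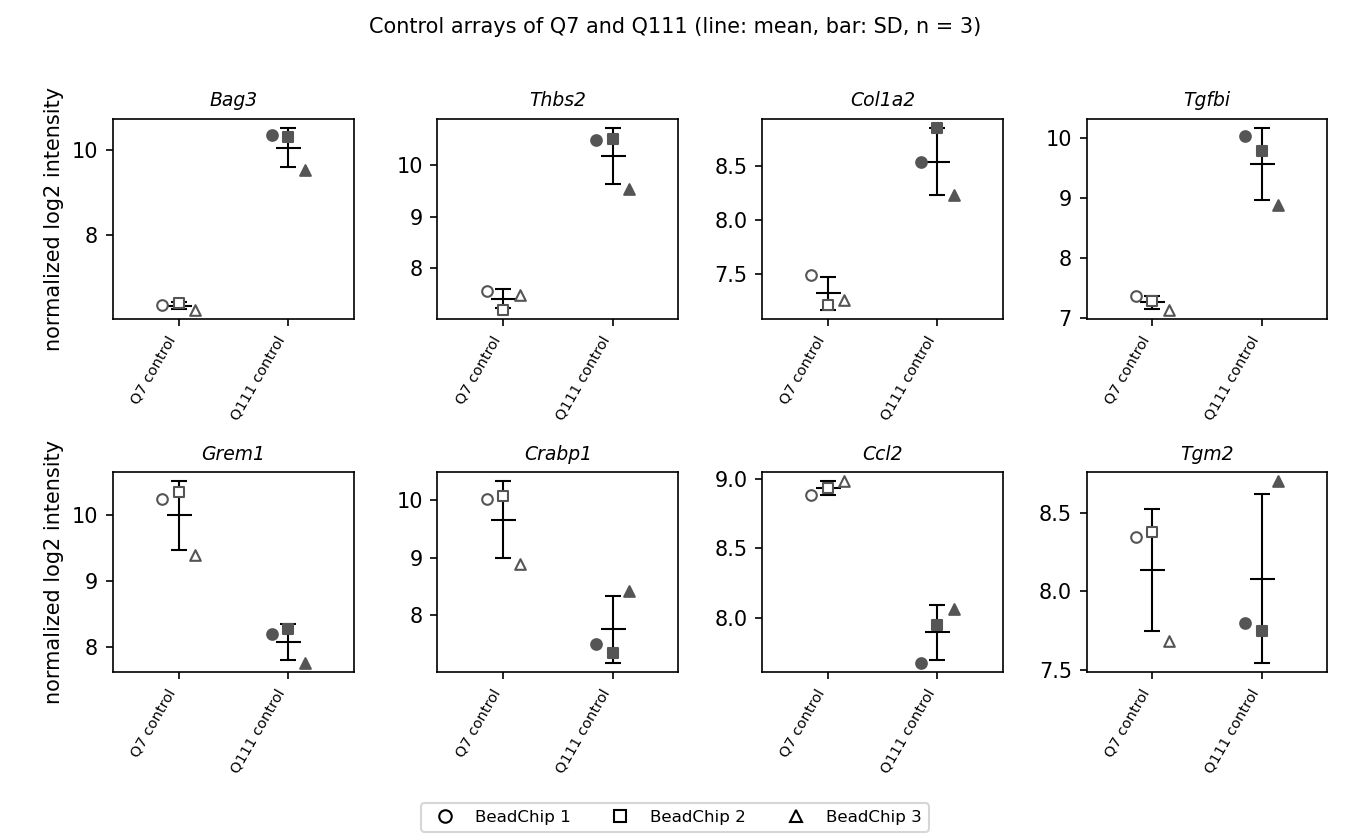
Normalized log2 intensity (y axis) of Bag3, Thbs2, Col1a2, Tgfbi, Grem1, Crabp1, Ccl2 and Tgm2 in untreated Q7 and Q111; each point is an array, shaped by BeadChip, and the bar is the mean with its SD. Bag3 lies at a mean of 6.328 in Q7 and 10.05 in Q111, and Tgm2 at 8.136 and 8.082.

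Across the 7 comparisons of lines and compounds, most lists that passed with the preset correlation of camera did not pass with an estimated one. Over all 12 comparisons 59 of 444 list tests passed, and 8 of these also with an estimated correlation. Those 8 covered NRF2 targets with cystamine in both lines, immediate early genes and metallothioneins with cystamine in Q111, and NF-kappaB genes with Boc-DON against control and with ZDON against Boc-DON in both lines. In no comparison did lists of the PGC-1alpha axis (smallest adjusted p = 0.323), oxidative phosphorylation (0.283), the TCA cycle (0.051) or glycolysis (0.211) pass the test. The same held for huntingtin and its partners (0.344), histone acetylation enzymes (0.436), polyamine metabolism (0.274), enzymes that use glutamine (0.25), apoptosis (0.377), hypoxia (0.323), S phase (0.145) and markers of striatal projection neurons (0.311), neural progenitors (0.211), neurons (0.275), astrocytes (0.56) and endothelial cells (0.0776). The interferon list (0.129) passed only with the block, for the difference in cystamine response between the lines.

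**Figure D3:**
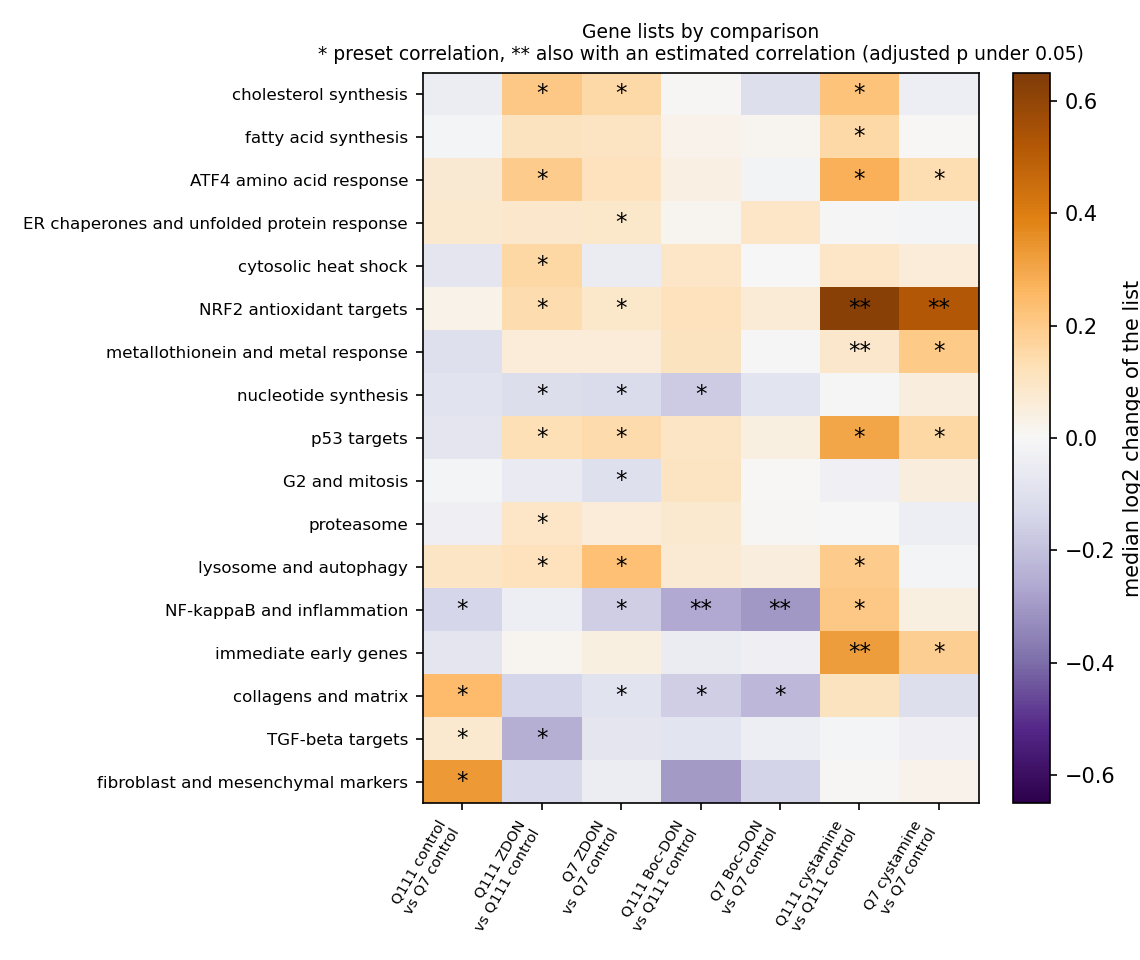
Median log2 change of each gene list (vertical axis) in the line comparison and in each compound against control in Q111 and Q7 (horizontal axis), as a colour scale; one star marks lists past adjusted p 0.05 with the preset correlation and a pair of stars those that passed with an estimated one as well. NRF2 targets under cystamine have the strongest colour, at 0.62 in Q111 and 0.52 in Q7.

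Cystamine was given at 250 µM, another dose than that of ZDON and Boc-DON, so its values stand beside theirs untested. It raised enzymes of detoxification and glutathione metabolism in both lines. Aldh3a1, an aldehyde dehydrogenase, rose by 3.02 in Q111 (SE 0.37, adjusted p = 6.59e-05) and by 2.94 in Q7 (SE 0.37, adjusted p = 0.000119). Glutathione S-transferase Gsta2 rose by 2.67 (SE 0.19, adjusted p = 4.19e-08) and 2.76 (adjusted p = 3.11e-08), Gsta1 by 2.45 (SE 0.19) and 2.30, and Gsta4 by 1.63 (SE 0.19) and 1.46. Prl2c2 rose by 2.70 (SE 0.20, adjusted p = 4.19e-08) in Q111 and 2.24 (adjusted p = 8.76e-07) in Q7. In Q111 63 genes changed, 46 upward and 17 downward, and in Q7 40 genes, 30 upward and 10 downward (n = 3 each). Of these, 24 changed in both lines and in the same direction, where 0.157 would be expected of independent lists, and none in opposite directions. With the replicate block the counts were 170 (130 upward) and 91 (66 upward), with 57 shared against 0.973 expected.

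NRF2 targets, the antioxidant genes, rose together. In Q111 12 of 28 rose over all genes and 20 adjusted over the list alone, with a median of 0.62 (adjusted p = 7.69e-34, and adjusted p = 0.000288 with an estimated correlation). In Q7 11 rose over all genes and 18 adjusted over the list alone, with a median of 0.52 (adjusted p = 3.43e-37, and adjusted p = 0.000166 with an estimated correlation). Members beside the transferases were thioredoxin reductase Txnrd1, up by 1.48 in Q111 (SE 0.17, adjusted p = 4.51e-05) and 1.03 in Q7 (adjusted p = 0.00362), and Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, up by 1.10 (SE 0.13) and 0.93. Sulfiredoxin Srxn1 rose by 1.25 and 1.29, the cystine transporter Slc7a11 by 1.06 (SE 0.16, adjusted p = 0.00147) and 1.38 (SE 0.16, adjusted p = 5.78e-05), and Nqo1 by 1.33 (SE 0.26, adjusted p = 0.0122) and 1.30 (adjusted p = 0.02). Haem oxygenase Hmox1 rose by 1.43 in Q111 (SE 0.25, adjusted p = 0.00592), and in Q7 it stood at 1.05 (adjusted p = 0.0842, blocked 0.000133). The list's medians by chip were 0.585, 0.716 and 0.62 in Q111 and 0.516, 0.52 and 0.719 in Q7.

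As a list, metallothionein and metal response genes were higher in Q111, with 2 of 10 members past the test over all genes and 4 adjusted over the list alone (median 0.0835, adjusted p = 0.00103, and adjusted p = 0.0221 with an estimated correlation; chip medians 0.0347, 0.219 and 0.271). In Q7 1 member rose, over all genes and adjusted over the list alone (median 0.203, adjusted p = 0.00735, and adjusted p = 0.0677 with an estimated correlation; chip medians 0.324, 0.197 and 0.18). Mt2 rose by 1.22 in Q111 (SE 0.17, adjusted p = 0.000517) and by 0.91 in Q7 (SE 0.17, adjusted p = 0.0132), while Mt1 stood at 0.01 (adjusted p = 0.985) and −0.0096 (adjusted p = 0.998). Mt3 rose by 1.22 in Q111 (SE 0.25, adjusted p = 0.0175) and stood at 0.57 in Q7 (adjusted p = 0.562). As a list, immediate early genes were higher in Q111, where 3 of 21 rose over all genes and 6 adjusted over the list alone (median 0.323, adjusted p = 4.31e-09, and adjusted p = 0.0221 with an estimated correlation), with chip medians of 0.403, 0.386 and 0.0957. In Q7 1 rose over all genes, and 4 rose and 1 fell adjusted over the list alone (median 0.186, adjusted p = 0.00113, and adjusted p = 0.272 with an estimated correlation), with chip medians of 0.103, 0.204 and 0.094. Fosl1, a subunit of the AP-1 transcription factor, rose by 1.02 (SE 0.16, adjusted p = 0.0015) and 1.08 (adjusted p = 0.00077). The MAP kinase phosphatases Dusp6 and Dusp4 rose by 0.85 (SE 0.16, adjusted p = 0.0104) and 0.62 (SE 0.14, adjusted p = 0.0477) in Q111. In Q7 they stood at 0.71 (adjusted p = 0.0557, blocked 0.00465) and 0.58 (adjusted p = 0.103, blocked 0.00563).

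As a list, ATF4 targets had a median of 0.275 in Q111 (adjusted p = 1.46e-08, and adjusted p = 0.137 with an estimated correlation), 3 of 28 over all genes and 8 adjusted over the list alone. In Q7 the median was 0.136 (adjusted p = 0.000472, and adjusted p = 0.672 with an estimated correlation), with 1 member past the test over all genes and 3 adjusted over the list alone. Slc7a11 belongs to this list too. Ddit4, an inhibitor of mTOR signalling, rose by 0.68 in Q111 (SE 0.13, adjusted p = 0.0144) and stood at 0.03 in Q7 (adjusted p = 0.998), and the glycine transporter Slc6a9 rose by 0.68 in Q111 (SE 0.15, adjusted p = 0.0378). The hormone Stc2 stood at 0.65 (adjusted p = 0.1, blocked 0.0023) in Q111. Targets of p53 had medians of 0.303 in Q111 (adjusted p = 1.72e-07, and adjusted p = 0.0949 with an estimated correlation) and 0.154 in Q7 (adjusted p = 5.94e-06, and adjusted p = 0.232 with an estimated correlation). Over all genes 1 of 20 rose in Q111 and 0 in Q7, and 5 and 6 adjusted over the list alone. Phlda3 rose by 0.78 in Q111 (SE 0.14, adjusted p = 0.00907), and the cell cycle inhibitor Cdkn1a stood at 1.08 in Q111 (SE 0.27, adjusted p = 0.0765, blocked 9.34e-07) and 0.82 in Q7 (adjusted p = 0.308, blocked 5.96e-05). The chip medians in Q111 were 0.224, 0.285 and 0.32 for ATF4 targets and 0.28, 0.323 and 0.271 for p53 targets. In Q7 they were 0.156, 0.12 and 0.134, and 0.297, 0.237 and 0.151.

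Further lists passed in Q111 by the preset test alone. All 17 genes of cholesterol synthesis were higher in sign, with Lss at 0.48, but 0 passed, adjusted over the list alone or over all genes (median 0.222, adjusted p = 0.00103, and adjusted p = 0.48 with an estimated correlation). Lysosome and autophagy genes had a median of 0.198 (adjusted p = 0.00251, and adjusted p = 0.602 with an estimated correlation), with 0 of 25 past the test over all genes and 5 adjusted over the list alone, among them the autophagy receptor Sqstm1 at 0.59 (SE 0.15, adjusted p = 0.075, blocked 0.00887). Genes of NF-kappaB and inflammation had a median of 0.207 (adjusted p = 0.0077, and adjusted p = 0.061 with an estimated correlation), with 0 of 17 over all genes and 3 adjusted over the list alone, and the prostaglandin synthase Ptgs2 stood at 0.98 (SE 0.26, adjusted p = 0.1, blocked 0.0133). Fatty acid synthesis had a median of 0.152 (adjusted p = 0.0214, and adjusted p = 0.137 with an estimated correlation), with 0 of 12 past either test and malic enzyme Me1 at 0.37 (SE 0.13, adjusted p = 0.263). On chip 3 the medians of cholesterol, lysosome and fatty acid genes were 0.00538, −0.0419 and 0.0154, against 0.278, 0.292 and 0.166 on chip 2 and 0.27, 0.326 and 0.127 on chip 1. NF-kappaB genes had 0.194, 0.108 and 0.175 on the 3 chips.

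Genes that fell with cystamine changed less. In Q111 they were Npr3, the clearance receptor of natriuretic peptides, at −1.14 (SE 0.24, adjusted p = 0.02), the calcium channel subunit Cacna1a at −0.63 (SE 0.14, adjusted p = 0.0398), Traf6 at −0.61, Tarsl2 at −0.60, Arxes2 at −0.59 and the Golgi gene Cog6 at −0.56 (SE 0.10, adjusted p = 0.0067). Second probes for Traf6 and Tarsl2 gave 0.113 and −0.0211. In Q7 Fam131a fell by 0.75 (SE 0.15, adjusted p = 0.0201), the synaptic vesicle gene Syngr3 by 0.73 (SE 0.12, adjusted p = 0.00406), Ppargc1a by 0.71 (SE 0.16, adjusted p = 0.0426), Arxes2 by 0.68, the chaperone Hspa2 by 0.62 and Stat5a by 0.61. Ppargc1a stood at −0.11 in Q111 (adjusted p = 0.865), and the difference between the lines was 0.60 (SE 0.22, 95% confidence interval 0.145 to 1.06, adjusted p = 1). With the block alone Slc1a3, a glutamate transporter of astrocytes, passed at −0.68 in Q111 (SE 0.57, blocked adjusted p = 0.0302) and −0.94 in Q7 (SE 0.57, blocked 0.00339). In the model without the block, leaving out cystamine replicate 3 turned its log2 change in Q111 to 0.0486 (adjusted p = 0.983 by limma). The block alone also brought Sorbs2 at −0.64 and Olfr684 at −0.60 in Q111, and Ranbp3l at −1.02 in Q7. Tgm2 stood at −0.08 (SE 0.30, adjusted p = 0.955) and −0.07 (SE 0.30, adjusted p = 0.998), and Htt at −0.07 and −0.09. Cycs stood at −0.026 in Q111 and −0.0084 in Q7, and Bdnf at −0.11 and −0.17.

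The number of genes changed by cystamine depended on single arrays, on the scaling and on the arrays in the model. In Q111 it was 32 without cystamine replicate 1, 31 without control replicate 2, 26 without control replicate 3, 225 without chip 3 and 37 (19 upward) with median scaling. In Q7 it was 23 without cystamine replicate 2, 86 without chip 3 and 14 (11 upward) with median scaling. With the arrays of the groups compared fitted alone it was 15 in Q111 and 12 in Q7, all upward, so that every fall named above lost its call. That setting ended the call of Syngr3 in Q7 (adjusted p = 0.203), which held in the others. It also ended those of Txnrd1 in Q7 (0.157) and of Mmp10 in Q111 (0.137) and Q7 (0.057), as did median scaling (0.0675, 0.173 and 0.0924). Median scaling moved the median of all genes by −0.111 in Q111 and −0.126 in Q7, against −0.0075 and −0.0083 with quantile normalization, so that its changes are relative to that shift. Leaving out 1 array ended, in Q111, the calls of Arxes2 (adjusted p up to 0.225, any array), Slc6a9 (up to 0.271, any but cystamine replicate 3), Dusp4 (up to 0.268, any array), Cacna1a (up to 0.262, any but cystamine replicate 1), Traf6 (up to 0.299, any but cystamine replicate 3) and Tarsl2 (up to 0.119, any but control replicate 1 and cystamine replicate 3). It also ended those of Mt3 (up to 0.171, control replicate 2 or 3 or cystamine replicate 1), Npr3 (up to 0.143, control replicate 1 or 2 or cystamine replicate 3) and Ddit4 (up to 0.128, control replicate 2 or 3 or cystamine replicate 3). Dusp6 lost its call without control replicate 3 or cystamine replicate 2 (up to 0.121), Phlda3 without control replicate 1 or cystamine replicate 2 (up to 0.0607) and Cog6 without control replicate 3 (0.0648). Hmox1 lost its call without control replicate 3 or cystamine replicate 1 (up to 0.0648) and Nqo1 without these or cystamine replicate 2 (up to 0.125). In Q7 the calls of Ppargc1a (up to 0.264, control replicate 1 or 3 or cystamine replicate 2 or 3), Stat5a (up to 0.134, any but control replicate 2) and Hspa2 (up to 0.236, any but control replicate 3 and cystamine replicate 1) ended. The same happened to Fam131a (up to 0.137, control replicate 2 or cystamine replicate 2 or 3), Arxes2 (up to 0.186, control replicate 1 or 3 or cystamine replicate 1 or 2) and Mt2 (up to 0.105, the same 4 arrays), and to Nqo1 (up to 0.149, control replicate 3 or cystamine replicate 1 or 2).

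**Figure D4:**
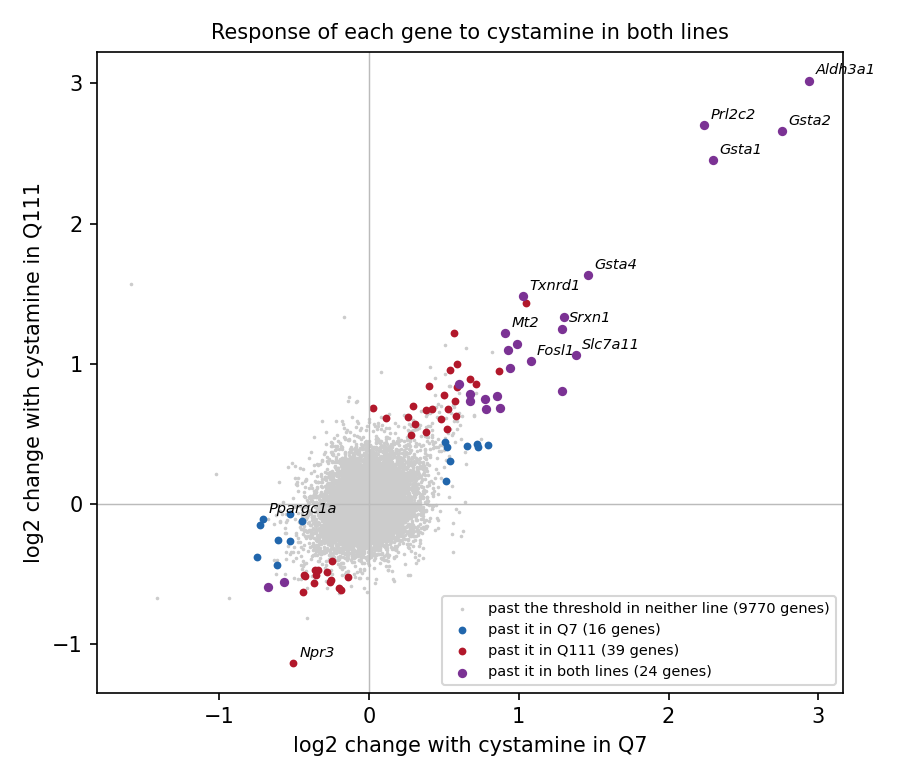
Log2 change with cystamine in Q7 (x axis) and in Q111 (y axis) for each of 9849 genes; colour marks the 24 genes past adjusted p 0.05 in both lines, the 16 in Q7 alone and the 39 in Q111 alone, and the rest passed in neither. The 24 shared genes changed in the same direction in both lines.

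Boc-DON at 50 µM lowered Cyp26b1, the enzyme that degrades retinoic acid, by 1.06 in Q111 (SE 0.12, adjusted p = 0.000246) and by 1.28 in Q7 (SE 0.14, adjusted p = 7.36e-05). It raised Slc46a3, a lysosomal transporter, by 0.86 (SE 0.12, adjusted p = 0.00231) and 0.89 (SE 0.13, adjusted p = 0.00795). In Q111 Lce1f, a gene of the late cornified envelope family, fell by 1.31 (SE 0.20, adjusted p = 0.00628), the matrix metalloprotease Mmp10 by 0.65 (SE 0.12, adjusted p = 0.047) and the lipid droplet gene Plin2 by 0.60 (SE 0.11, adjusted p = 0.0418), and Bbs9 rose by 0.52 (SE 0.10, adjusted p = 0.047), with 0.0193 at a second probe. In Q7 the blocked estimates were −1.27 for Lce1f (blocked adjusted p = 0.000521; −1.14 and adjusted p = 0.0984 without the block), −0.68 for Mmp10 (0.0342) and −0.60 for Plin2 (0.0418). Those of Cyp26b1 and Slc46a3 were −1.33 and 0.86. These were the 6 genes that passed in Q111 (n = 3 each) and the 2 in Q7 (n = 2 and 3). With the block 79 passed in Q111 (20 upward) and 25 in Q7 (2 upward), with 14 shared against 0.142 expected of independent lists, all in the same direction.

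The list of inflammatory genes was lower with Boc-DON in both lines. The median of the 17 NF-kappaB and inflammation genes was −0.261 in Q111 (adjusted p = 0.00147, and adjusted p = 0.0337 with an estimated correlation) and −0.303 in Q7 (adjusted p = 8.18e-09, and adjusted p = 0.000471 with an estimated correlation). Over all genes 0 passed in either line, and 3 in Q111 and 7 in Q7 were lower when adjusted over the list alone. Chip medians were −0.283, −0.342 and −0.16 in Q111 and −0.441 and −0.329 in Q7, where the blocked median was −0.397. The chemokine Cxcl1 stood at −0.78 in Q111 (SE 0.16, adjusted p = 0.0619, blocked 0.00195) and −0.91 in Q7 (SE 0.18, adjusted p = 0.0984), where its blocked estimate was −1.0 (blocked adjusted p = 0.000521). Blocked estimates of Traf1 were −0.60 in Q111 (0.00485) and −0.69 in Q7 (0.00455), and of Ccl7 −0.71 (0.0359) and −0.85 (0.0423). The list of collagens and matrix genes had medians of −0.159 in Q111 (adjusted p = 0.00841, and adjusted p = 0.709 with an estimated correlation; chip medians −0.149, −0.113 and −0.247) and −0.219 in Q7 (adjusted p = 0.0034, and adjusted p = 0.883 with an estimated correlation; chip medians −0.293 and −0.111; blocked median −0.343). In either line 0 of these 28 genes passed, adjusted over the list alone or over all genes, with Thbs1 at −1.04 in Q111 (SE 0.32, adjusted p = 0.251). Nucleotide synthesis passed as a list in Q111 (median −0.171, adjusted p = 0.00159, and adjusted p = 0.709 with an estimated correlation; chip medians −0.199, −0.127 and −0.124). Of these 18 genes 0 passed over all genes and 2 adjusted over the list alone, Dctd at −0.52 (SE 0.11, adjusted p = 0.0689, blocked 0.0216) and Atic at −0.49 (SE 0.11, adjusted p = 0.0955, blocked 0.0433).

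Other genes passed with the block alone under Boc-DON. In Q111 Sptssa stood at 0.74 (SE 0.30), Rassf4 at 0.74 (SE 0.16), Lrp11 at 0.72 (SE 0.14), Nxt2 at 0.60 and Mindy2 at 0.57. Lower were Ly6c1 at −0.90 (SE 0.21), Ccn5 at −0.86, the water channel Aqp5 at −0.86 and Tnnt2 at −0.79. In Q7 the blocked estimates were 0.83 for Spats1, −1.16 for Prl2c2 (blocked adjusted p = 0.027; −1.13, SE 0.22 and adjusted p = 0.0984 without the block), −1.36 for Ranbp3l and −0.81 for Pcsk4. By lists, the block alone brought TGF-beta targets (median −0.0827, blocked adjusted p = 0.0441, and 0.56 with an estimated correlation) and fibroblast markers (−0.295, 0.0441 and 0.56) past the test in Q111. In Q7 it brought cholesterol synthesis (blocked median −0.151, 0.0165 and 0.66) and fibroblast markers (−0.244, 0.042 and 0.66). Tgm2 stood at −0.40 in Q111 (SE 0.30, adjusted p = 0.732) and −0.24 in Q7 (SE 0.33, adjusted p = 0.883), Htt at 0.12 and 0.28, Ppargc1a at 0.15 and −0.25, Cycs at 0.21 and −0.12, and Bdnf at −0.21 and −0.18. Blocked, the values in Q7 were −0.11 for Tgm2, 0.23 for Htt, −0.27 for Ppargc1a, −0.0128 for Cycs and −0.15 for Bdnf. The count in Q111 was 37 without chip 3, 2 without control replicate 1 or 2 or Boc-DON replicate 3, and 3 without any other array of the pair of groups. In Q7 it was 52 without chip 3 and 1 without control replicate 1 or 3 or Boc-DON replicate 1. Slc46a3 kept its call in Q111 in every setting but lost it in Q7 without control replicate 1 (adjusted p = 0.0891) or 3 (0.0611) or Boc-DON replicate 1 (0.165) or 2 (0.296). In Q111 Mmp10 (up to 0.288), Plin2 (up to 0.144) and Bbs9 (up to 0.242) lost theirs without any 1 array, and Lce1f (up to 0.0746) without control replicate 1 or 2 or Boc-DON replicate 3. Cyp26b1 lost its call only when the arrays of the groups compared were fitted alone (0.083 in Q111 and 0.0764 in Q7).

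ZDON at 50 µM changed few single genes when each line was tested alone. In the sum of the responses of both lines, taken from a regrouping described below, 55 genes passed by limma. In Q7 Lce1f fell by 1.23 (SE 0.20, adjusted p = 0.0431) and the ribosomal protein gene Rpl22 by 0.61 (SE 0.10, adjusted p = 0.0473), the only 2 of 9849 genes to pass (n = 3 each). One array of this group stood apart, Q7 ZDON replicate 3, where the probe for 18S ribosomal RNA read 4531.3 intensity units against 14244.6 to 27122.2 on the other arrays. In Q111 0 genes passed by limma, where 680 had an unadjusted p under 0.05 against 492 expected, and the smallest adjusted p was 0.0693. Lce1f stood there at −1.08 (SE 0.20, adjusted p = 0.0693, blocked 0.00108) and Rpl22 at −0.39 (adjusted p = 0.278). With the block 18 genes passed in Q111 (11 upward) and 5 in Q7 (2 upward), with 3 shared against 0.00437 expected. The shared genes were Lce1f, Cdkn1a, at 0.79 in Q111 (SE 0.27, blocked adjusted p = 0.00108) and 0.58 in Q7 (SE 0.27, blocked 0.022), and Hmox1, at 0.75 (SE 0.25, blocked 0.0189) and 0.83 (SE 0.25, blocked 0.0127). Others in Q111 with the block were Lrp11 at 0.76 (SE 0.14), Slc7a11 at 0.76 (SE 0.16, blocked 0.0236), Fkbp14 at 0.64, Calr3 at 0.63, Krtap1-5 at −0.71, Cacna1a at −0.71 (SE 0.14, blocked 0.0189), the tendon transcription factor Scx at −0.68, Aoc3 at −0.65 and Klk10 at −0.62. Other probes for Calr3 gave −0.0675, 0.0132 and 0.788. In Q7 Chodl passed with the block, at −0.92 (SE 0.40, blocked 0.0127).

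Stress response lists had higher medians with ZDON in Q111 by the preset test, and none of them passed with an estimated correlation. ATF4 targets had a median of 0.195 (adjusted p = 1.73e-08, and adjusted p = 0.387 with an estimated correlation), with 0 of 28 genes past the test over all genes and 3 adjusted over the list alone. Their examples were Slc7a11 and Slc6a9, the latter at 0.58 (SE 0.15, adjusted p = 0.232, blocked 0.0236). Cytosolic heat shock genes had 0.155 (adjusted p = 0.00187, and adjusted p = 0.222 with an estimated correlation), with 0 of 18 and 2, Hspa4l at 0.72 (SE 0.17, adjusted p = 0.174) and Hsph1 at 0.43 (SE 0.10, adjusted p = 0.174). NRF2 targets had 0.142 (adjusted p = 0.000559, and adjusted p = 0.41 with an estimated correlation), with 0 of 28 and 5, and Gclm at 0.56 (SE 0.13, adjusted p = 0.174, blocked 0.0402). Targets of p53 had 0.128 (adjusted p = 0.00132, and adjusted p = 0.41 with an estimated correlation), with 0 of 20 and 5, Trp53inp1 at 0.81 (SE 0.20, adjusted p = 0.212) and Mdm2 at 0.61 (adjusted p = 0.421). Proteasome genes had 0.0955 (adjusted p = 0.00218, and adjusted p = 0.41 with an estimated correlation), with 25 of 28 higher in sign. Lower were TGF-beta targets, at −0.244 (adjusted p = 0.00276, and adjusted p = 0.41 with an estimated correlation) with Id1 at −0.34 (SE 0.12), and nucleotide synthesis at −0.111 (adjusted p = 0.0161, and adjusted p = 0.417 with an estimated correlation). Cholesterol synthesis (0.208, adjusted p = 0.0353) and lysosome genes (0.115, adjusted p = 0.046) each had adjusted p = 0.544 with an estimated correlation. Of the proteasome, TGF-beta, nucleotide, cholesterol and lysosome genes 0 passed, adjusted over the list alone or over all genes. The block alone brought collagens and matrix past the test (−0.139, blocked adjusted p = 0.0264, and 0.557 with an estimated correlation). Chip medians were 0.209, 0.293 and 0.189 for ATF4 targets, 0.104, 0.0928 and 0.25 for heat shock, 0.105, 0.248 and 0.0895 for NRF2 targets and 0.144, 0.127 and 0.267 for p53 targets. They were 0.0993, 0.107 and 0.114 for the proteasome, −0.216, −0.189 and −0.265 for TGF-beta targets and −0.0431, −0.0775 and −0.212 for nucleotide synthesis. Cholesterol genes had 0.226, 0.215 and −0.00479 and lysosome genes 0.091, 0.231 and 0.0512.

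With ZDON in Q7, 24 of 25 lysosome and autophagy genes were higher in sign and 0 passed, with a median of 0.233 (adjusted p = 8.54e-07, and adjusted p = 0.387 with an estimated correlation; chip medians 0.235, 0.242 and 0.181). Sqstm1 stood at 0.50 (SE 0.15, adjusted p = 0.563) and the lysosomal channel Mcoln1 at 0.43 (adjusted p = 0.709). NRF2 targets had 0.0904 (adjusted p = 0.00227, and adjusted p = 0.387 with an estimated correlation; chips 0.167, 0.0425 and 0.128) and p53 targets 0.143 (adjusted p = 0.00504, and adjusted p = 0.457 with an estimated correlation; chips 0.223, 0.348 and −0.0774), with 3 and 2 genes past the test adjusted over the list alone. Cholesterol synthesis had 0.148 (adjusted p = 0.00504, and adjusted p = 0.543 with an estimated correlation; chips 0.181, 0.291 and 0.0729). Chaperones of the endoplasmic reticulum had 0.0872 (adjusted p = 0.0315, blocked 0.0507, and adjusted p = 0.238 with an estimated correlation; chips 0.137, 0.0907 and 0.071). Lower were nucleotide synthesis, 17 of 18 in sign, at −0.119 (adjusted p = 0.00227, and adjusted p = 0.387 with an estimated correlation; chips −0.174, −0.115 and 0.0887) and genes of G2 and mitosis at −0.101 (adjusted p = 0.0109, and adjusted p = 0.429 with an estimated correlation; chips −0.112, −0.101 and −0.127). NF-kappaB genes stood at −0.158 (adjusted p = 0.0257, and adjusted p = 0.238 with an estimated correlation; chips −0.193, −0.149 and −0.223) and collagens and matrix at −0.0864 (adjusted p = 0.043, and adjusted p = 0.682 with an estimated correlation; chips −0.0834, 0.0566 and −0.154). ATF4 targets passed with the block alone (0.112, blocked adjusted p = 0.0107, and 0.376 with an estimated correlation). In these lists 0 genes passed over all genes, and outside NRF2 and p53 targets 0 adjusted over the list alone.

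With ZDON Tgm2 stood at −0.28 in Q111 (SE 0.30, adjusted p = 0.917) and −0.13 in Q7 (SE 0.30, adjusted p = 0.999), Htt at 0.18 and 0.24, Ppargc1a at 0.22 and 0.16, Cycs at 0.17 and 0.018, and Bdnf at 0.068 in Q111 (adjusted p = 0.964). Without chip 3 ZDON changed 10 genes in Q111 and 106 in Q7. The count in Q111 was 3 without ZDON replicate 3 and 1 without control replicate 3. In Q7 both calls ended without any 1 array, with Lce1f at an adjusted p of up to 0.561 and Rpl22 of up to 0.651, and 500 genes there had an unadjusted p under 0.05.

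**Figure D5:**
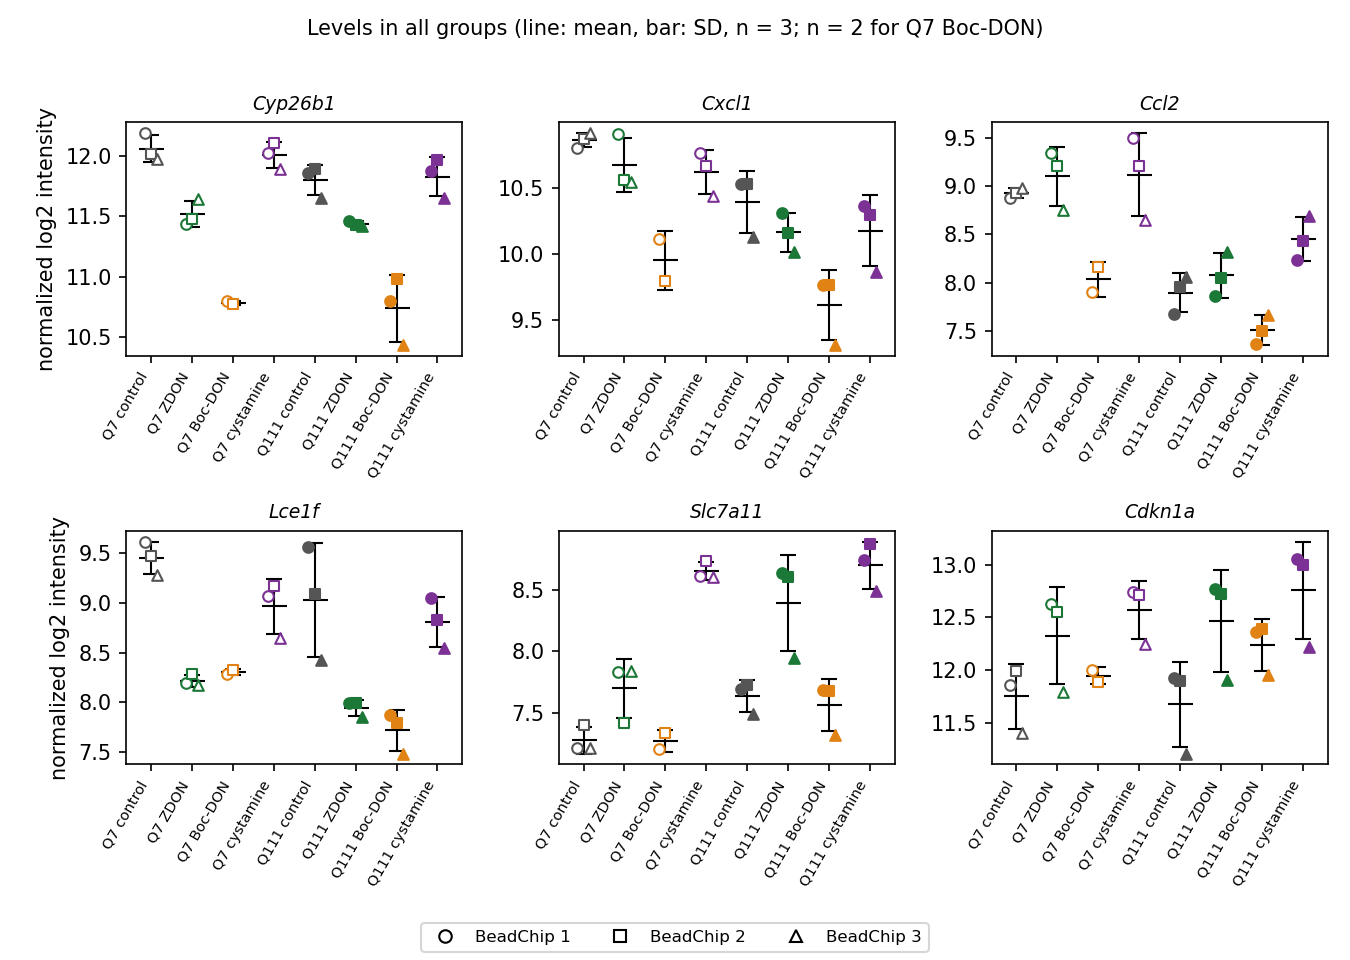
Normalized log2 intensity (y axis) of Cyp26b1, Cxcl1, Ccl2, Lce1f, Slc7a11 and Cdkn1a in the 8 groups (x axis); points are arrays, shaped by BeadChip, and bars are means with their SD. Cyp26b1 is lowest with Boc-DON, at 10.74 in Q111 and 10.78 in Q7 against 11.80 and 12.06 in the controls.

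ZDON and Boc-DON, given at the same dose and time, were compared directly within each line. In Q7 the arrays of chip 3 hold ZDON but not Boc-DON, so blocked estimates are given there beside or in place of the others. By limma 0 genes differed in Q111, with 380 at an unadjusted p under 0.05, and 0 in Q7, with 646, against 492 expected by chance. With the block these were 579 and 895, and 6 genes were higher with ZDON than with Boc-DON in Q111, and 18 differed in Q7, 15 of them higher with ZDON. Cyp26b1 was among them in both, at 0.70 in Q111 (95% confidence interval 0.446 to 0.956, adjusted p = 0.115, blocked 0.0231) and 0.74 in Q7 (0.451 to 1.02, adjusted p = 0.129), where the blocked estimate was 0.79 (blocked adjusted p = 0.008). In Q111 Slc7a11 stood at 0.83 (0.497 to 1.17, blocked 0.0236), Angptl4 at 0.74 (0.457 to 1.03, blocked 0.0231) and Cdx2 at 0.61 (blocked 0.0236). In Q7 the blocked estimates were 1.23 for the chemokine Ccl7 (blocked adjusted p = 0.008, and adjusted p = 0.378 without the block), 1.07 for Ccl2 (0.0443 and 0.132) and 0.82 for Cxcl1 (0.008 and 0.378), and −0.64, −0.55 and −0.55 for the histone genes H2bc11, H2bc22 and H2bc15. Tgm2 differed by 0.12 in Q111 (−0.495 to 0.732, adjusted p = 1) and 0.11 in Q7 (−0.576 to 0.796, adjusted p = 0.955), where the block turned its sign, to −0.0148 (blocked adjusted p = 0.99). The other genes named in advance had Htt at 0.06 and −0.04, Ppargc1a at 0.07 and 0.41, Cycs at −0.05 and 0.13, and Bdnf at 0.28 and 0.18. In Q7 the block turned Htt to 0.01 and left 0.43 for Ppargc1a, 0.0311 for Cycs and 0.15 for Bdnf. Without chip 3 the counts were 9 and 125. In Q111 1 gene differed without Boc-DON replicate 2 or ZDON replicate 3, and in Q7 1 without ZDON replicate 3.

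The list of NF-kappaB and inflammation genes was higher with ZDON than with Boc-DON in both lines, with medians of 0.145 in Q111 (adjusted p = 0.000112, and adjusted p = 0.0146 with an estimated correlation; chips 0.191, 0.202 and 0.149) and 0.133 in Q7 (adjusted p = 0.000405, and adjusted p = 0.0256 with an estimated correlation; chips 0.294 and 0.31, blocked median 0.234). Of its genes 0 passed over all genes and 3 in each line adjusted over the list alone. Cholesterol synthesis was higher too, at 0.161 in Q111 (adjusted p = 0.00102, and adjusted p = 0.382 with an estimated correlation; chips 0.186, 0.207 and 0.0393) and 0.308 in Q7 (adjusted p = 8.84e-05, and adjusted p = 0.672 with an estimated correlation; chips 0.372 and 0.464, blocked median 0.386), with Lss at 0.65 in Q7 (SE 0.26, adjusted p = 0.735) and at 0.82 with the block (SE 0.15, blocked adjusted p = 0.0328). Immediate early genes had 0.17 in Q111 (adjusted p = 0.000126, and adjusted p = 0.154 with an estimated correlation; chips 0.0871, 0.229 and 0.165) and 0.103 in Q7 (adjusted p = 0.0301, and adjusted p = 0.736 with an estimated correlation; chips 0.258 and 0.178, blocked median 0.184). In Q111 ATF4 targets had 0.184 (adjusted p = 4.75e-08, and adjusted p = 0.154 with an estimated correlation; chips 0.213, 0.196 and 0.146), tRNA synthetases 0.132 (adjusted p = 0.000233, and adjusted p = 0.114 with an estimated correlation; chips 0.215, 0.205 and −0.000714) and NRF2 targets 0.0565 (adjusted p = 0.0343, blocked 0.0507, and adjusted p = 0.495 with an estimated correlation; chips 0.0943, 0.122 and 0.00916). Lower there were genes of G2 and mitosis, at −0.107 (adjusted p = 0.000233, and adjusted p = 0.154 with an estimated correlation; chips −0.135, −0.186 and −0.116), and ribosomal proteins, at −0.0587 (adjusted p = 0.0203, and adjusted p = 0.692 with an estimated correlation; chips −0.0312, −0.0249 and −0.107). In Q7 lysosome genes had 0.0849 (adjusted p = 0.00905, and adjusted p = 0.853 with an estimated correlation; chips 0.209 and 0.194, blocked median 0.2) and REST targets with Bdnf 0.182 (adjusted p = 0.0442, and adjusted p = 0.62 with an estimated correlation; chips 0.109 and 0.11, blocked median 0.153). The block alone brought p53 targets past the test in Q111 (0.0812, blocked adjusted p = 0.0249, and 0.339 with an estimated correlation). In Q7 it brought ATF4 targets (blocked median 0.115, blocked adjusted p = 0.00128, and 0.23 with an estimated correlation), p53 targets (0.14, 0.00492 and 0.231), NRF2 targets (0.0913, 0.00732 and 0.193), G2 and mitosis (−0.157, 0.00255 and 0.193), fatty acid synthesis (0.0971, 0.0406 and 0.193) and collagens (0.163, 0.0229 and 0.784).

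Whether a compound acted differently in Q111 than in Q7 was tested by interaction terms, and by limma 0 genes passed for ZDON, Boc-DON or cystamine, with or without the block. At an unadjusted p under 0.05 there were 212, 318 and 396 genes, against 492 expected. With the block there were 395, 464 and 606. The interaction for Cyp26b1 with Boc-DON was 0.22 and for Cxcl1 0.13 (both adjusted p = 0.999; blocked 0.27 and 0.22, both blocked adjusted p = 0.972), and with cystamine that for Prl2c2 was 0.46, for Txnrd1 0.45 and for Npr3 −0.63 (all adjusted p = 1). Ddit4, with 0.65 for cystamine and 0.56 for ZDON, had an adjusted p of 1 in each. By lists, the response to ZDON was higher in Q111 for ATF4 targets (median 0.156, adjusted p = 0.0084, and adjusted p = 0.912 with an estimated correlation) and heat shock genes (0.135, adjusted p = 0.0311, and adjusted p = 0.607 with an estimated correlation). It was lower for TGF-beta targets (−0.192, adjusted p = 0.037, and adjusted p = 0.912 with an estimated correlation). The response to cystamine was higher for cholesterol synthesis (0.248, adjusted p = 0.00096) and lysosome genes (0.21, adjusted p = 0.0203), each with adjusted p = 0.688 with an estimated correlation, and for Boc-DON 0 of 37 lists passed. Chip medians were 0.145, 0.251 and −0.0758 for ATF4 targets, 0.11, −0.0126 and 0.13 for heat shock, −0.232, −0.365 and −0.18 for TGF-beta, 0.347, 0.364 and −0.0775 for cholesterol and 0.316, 0.284 and 0.0494 for lysosome genes. With the block alone lysosome genes passed for ZDON (−0.13, blocked adjusted p = 0.0441, and 0.704 with an estimated correlation). For cystamine the block brought interferon genes (0.219, blocked 0.0396 and 0.311), immediate early genes (0.15, 0.0396 and 0.311), fatty acid synthesis (0.156, 0.0458 and 0.311), collagens (0.169, 0.0458 and 0.668) and ATF4 targets (0.113, 0.0468 and 0.601). Tgm2 had interactions of −0.16 for ZDON (SE 0.42), −0.16 for Boc-DON (SE 0.44) and −0.0049 for cystamine (SE 0.42). Those of Htt were −0.05, −0.16 and 0.01, of Cycs 0.15, 0.33 and −0.02, and of Bdnf 0.07, −0.02 and 0.07. Ppargc1a had 0.05 for ZDON and 0.40 for Boc-DON. Blocked, the interactions with Boc-DON were −0.29 for Tgm2, −0.11 for Htt, 0.23 for Cycs, −0.0538 for Bdnf and 0.42 for Ppargc1a. Without chip 3, 7 genes passed for cystamine.

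The last question was whether the compounds moved Q111 expression towards Q7. Because the untreated Q111 arrays enter both the line comparison and each compound effect, the line genes were taken from the arms of the other compounds, which share no array with the effect tested. Of such genes 50.6% moved towards Q7 with ZDON (539 genes), 48.0% with Boc-DON (475 genes) and 54.5% with cystamine (310 genes), where 50 is no preference. In Q7 itself, the same genes moved in the direction of Q7 in 42.7%, 44.8% and 59.0% of cases, and those of the blocked model in 42.2%, 50.9% and 58.9%. By camera in Q111, genes higher in Q111 had a median of −0.0319 with ZDON (p = 0.0209, and p = 0.538 with an estimated correlation), −0.0265 with Boc-DON (p = 0.399) and −0.0373 with cystamine (p = 0.88). Genes lower in Q111 had −0.0283 with ZDON (p = 0.0549), −0.0671 with Boc-DON (p = 4.9e-05, and p = 0.123 with an estimated correlation), which is away from Q7, and 0.0132 with cystamine (p = 0.0488, and p = 0.498 with an estimated correlation). Line genes were also taken from the blocked model. By camera with the block those higher in Q111 had −0.0132 with ZDON (p = 0.167, and p = 0.645 with an estimated correlation), −0.00936 with Boc-DON (p = 0.273) and 0.00811 with cystamine (p = 0.115). By camera those lower had −0.0299 with ZDON (p = 0.0304, and p = 0.479 with an estimated correlation), −0.0591 with Boc-DON (p = 1.39e-05, and p = 0.072) and 0.0133 with cystamine (p = 0.0584). Blocked, the shares in Q111 were 48.0%, 46.4% and 50.3%, and without chip 3 they were 49.5%, 51.8% and 49.0%. With median scaling, which moved the median of all genes by −0.111 with cystamine in Q111, they were 50.9%, 57.1% and 68.3%. The side of 50 changed with ZDON without control replicate 1 (40.7%) or 2 (48.2%) or ZDON replicate 3 (40.4%), and with Boc-DON without Boc-DON replicate 1 (52.6%) or 2 (54.9%) or control replicate 3 (60.5%). With cystamine it changed without control replicate 1 (48.1%) or 2 (47.7%) or cystamine replicate 3 (36.8%).

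Taken from the untreated arrays instead, the 153 line genes had compound effects of the opposite sign in 70.6% of cases with ZDON, 62.7% with Boc-DON and 68.0% with cystamine. Simulated data with the shared controls and no compound effect gave 68.4% (65.1% to 72.1%), 68.3% (65.7% to 72.5%) and 68.6% (65.9% to 72.3%). With the chip differences of the data in the simulation, the ranges were 64.1% to 74.7%, 61.2% to 73.9% and 62.0% to 75.2%. With the block the shares were 69.5%, 64.8% and 64.8% of 318 line genes, and the simulated ranges 64.1% to 72.5%, 64.7% to 72.2% and 62.3% to 72.6%. These simulations took the measured line differences as true. They called more line genes than the data, with means of 330, 333 and 330, and with the block 934, 938 and 927. The covariance of the line difference and the compound effect across genes, which are not independent replicates, was −0.0142, −0.0118 and −0.0128, against −0.0104, −0.0103 and −0.0104 simulated. Among genes past the test in both, cystamine moved Ddit4, Dyrk3, Mmp10, Prl2c2, Rgs16, Slc20a2 and Ssbp2 against the line difference, and Osgin1 with it. Independent lists would give 0.408 and 0.57, and simulations with shared controls and no compound effect gave 0.04 in opposite directions, but neither allows for shared controls beside a real compound effect. Without untreated Q111 replicate 2, at least 1 of the calls of Ddit4, Dyrk3, Osgin1, Rgs16, Slc20a2 and Ssbp2 ended (adjusted p up to 0.133, for Osgin1), and without replicate 3 the same held for these genes except Rgs16 (up to 0.192, for Slc20a2). Of these Prl2c2 was lower by 1.72 in untreated Q111 and rose by 2.70 with cystamine in Q111, and by 2.24 in Q7.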

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

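In this part the tests of probes without a gene symbol and of which arrays the ZDON regrouping exchanged were chosen after the results were seen, and the interaction tests and the splits of the samples were planned.

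The response to ZDON differed between the lines by the interaction test for 3 lists, with medians of 0.156 for ATF4 targets (0.195 in Q111 and 0.112 in Q7, adjusted p = 0.0084, and 0.912 with an estimated correlation), 0.135 for cytosolic heat shock (0.155 and −0.0502, adjusted p = 0.0311, and 0.607) and −0.192 for TGF-beta targets (−0.244 and −0.0783, adjusted p = 0.037, and 0.912). The response to cystamine differed for cholesterol synthesis, by 0.248 (0.222 in Q111 and −0.0392 in Q7, adjusted p = 0.00096, and 0.688 with an estimated correlation), and for lysosome and autophagy, by 0.21 (0.198 and −0.0122, adjusted p = 0.0203, and 0.688). By single genes the real grouping gave 0, by limma, for ZDON and for cystamine, which all 100 regroupings of treated and control arrays within the lines reach by design, so that this test decides nothing about chance. The highest of the others was 6 for cystamine and 55 for ZDON. The 55 came from a regrouping that exchanged all ZDON and control arrays of Q7 and so measured the sum of the responses of both lines. They are therefore genes with a ZDON effect pooled over the lines, not with a difference between them. Across genes, which are not independent replicates, the ZDON responses of the lines had a correlation of 0.312, with no array in common.

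Probes without a gene symbol carried signal too. Of 2545 tested, 17 differed between untreated Q111 and Q7 (7 higher, 10 lower), and 3 rose with cystamine in Q111 and 3 in Q7.

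With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 of the 10 splits reached the real count in the line comparison (153, highest other 0), with Boc-DON in Q111 (6, 0), with cystamine in Q111 (63, 0) and in Q7 (40, 0) and with ZDON in Q7 (2, 1). All 10 reached the 0 of ZDON in Q111 and of ZDON against Boc-DON in Q111, as they must, and the highest other was 0 as well. For lists, 1 split reached the real count in the line comparison (4, highest other 3), with ZDON in Q111 (9, 8) and in Q7 (9, 4) and with cystamine in Q7 (5, 2). With Boc-DON in Q111 (3, highest other 5) and cystamine in Q111 (9, 18) 4 splits did so, and for ZDON against Boc-DON in Q111 (8, 10) 2 splits. Among the splits that part all 3 pairs of a chip, as the real one does, the highest others for lists were 3 in the line comparison, 2 with ZDON, 0 with Boc-DON and 9 with cystamine in Q111, 4 with ZDON and 2 with cystamine in Q7, and 7 for ZDON against Boc-DON. For genes they were 0 in each. The other splits keep the arrays of at least 1 chip on the same side, so that differences between chips enter them.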

How the results depend on the processing

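Leaving out chip 3, the block joined with an estimated correlation, and the list tests under other normalizations, filters or arrays were tests chosen after seeing the data, and the rest were planned. The signal limits genes near the array median, and 3 arrays per group limit the rest. Of 92 results past the threshold (64 named genes, each counted per comparison), 37 kept their call in every setting, 55 lost it in at least 1 (49 with the arrays of the groups compared alone, 32 with median scaling) and 0 reversed. The causes of the changes were not tested. With the replicate block the counts of genes were 318 between the lines. In Q111 they were 18 with ZDON, 79 with Boc-DON and 170 with cystamine, in Q7 5, 25 and 91, and for ZDON against Boc-DON 6 in Q111 and 18 in Q7. All genes called without the block kept their call with it. Of 59 list calls 57 held, of 77 with the block, and those lost were ER chaperones with ZDON in Q7 and NRF2 targets for ZDON against Boc-DON in Q111. For sets of line genes in Q111 the block ended p under 0.05 for those higher with ZDON (0.167) and lower with cystamine (0.0584), and brought it for those lower with ZDON (0.0304). Without chip 3 the counts were 392, then 10, 37 and 225 in Q111, 106, 52 and 86 in Q7, 9 and 125 for ZDON against Boc-DON, and 7 for the cystamine interaction. With the arrays of the groups compared alone they were 88 between the lines, 2 with Boc-DON and 15 with cystamine in Q111, and 1, 0 and 12 in Q7, with all of cystamine upward. Median scaling gave 3 with Boc-DON and 37 with cystamine in Q111, 1, 1 and 14 in Q7, and 2 for ZDON against Boc-DON in Q111. With no filter Boc-DON in Q111 gave 3 and ZDON in Q7 gave 1. No background correction and the deposited values changed only the counts with cystamine, to 66 in Q111 and 42 in Q7.

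Without each array in turn the counts ran from 73 (Q111 control replicate 2) to 160 (Q111 control replicate 3) between the lines. In Q111 they ran from 0 to 3 with ZDON, 2 to 3 with Boc-DON and 26 (Q111 control replicate 3) to 94 (Q111 cystamine replicate 3) with cystamine, and in Q7 they were 0 throughout with ZDON, 1 to 2 with Boc-DON and 23 to 36 with cystamine. For ZDON against Boc-DON they ran from 0 to 1 in either line, and for each interaction they were 0. Of the 59 list calls, 8 held with an estimated correlation and 14 with that and the block, and all 59 medians kept their sign in the 8 settings run for lists, 2 of which cannot change them alone. The share of line genes that moved towards Q7 was, with ZDON, 48.0% with the block, 49.8% with no background correction and with the deposited values, and 49.5% without chip 3. With Boc-DON it was 57.1% with median scaling and 51.8% without chip 3, and with cystamine 68.3% and 49.0%. Without each array it ran from 40.4% to 62.3%, 37.5% to 60.5% and 36.8% to 65.7%. Signs turned by more than the SE for some genes not past the threshold without the block, and by less for Tgm2 and Htt in ZDON against Boc-DON in Q7 with the block (−0.0148 and 0.01). Without each array Tgm2 ran from −0.56 to 0.0246 with ZDON and −0.39 to 0.23 with cystamine in Q111, Bdnf from −0.0907 to 0.20 with ZDON in Q111, Slc1a3 from −1.18 to 0.0486 with cystamine in Q111, Cycs from −0.22 to 0.064 with Boc-DON and −0.11 to 0.17 with cystamine in Q7, and Stmn2 from −0.0398 to 0.44 for ZDON against Boc-DON in Q7. Without chip 3 Cycs with Boc-DON in Q7 was 0.064, and the ZDON interactions of Ppargc1a and Bdnf were −0.23 and −0.14.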

Other observations

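In this part the tests of shared controls, of the moves towards Q7 as a cause of opposite signs, of a compressed scale, of Q7 material on chip 3 and of both Bag3 explanations, and the overlaps of the compounds within a line, were chosen after the results were seen.

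Boc-DON and cystamine moved several genes in opposite directions, although a shared control pushes a pair of effects towards the same sign. Slc46a3 rose by 0.86 in Q111 and 0.89 in Q7 with Boc-DON (blocked 0.86) and fell by 0.56 (SE 0.12, adjusted p = 0.0286) and 0.57 (adjusted p = 0.0323) with cystamine. Mmp10 fell by 0.65 with Boc-DON in Q111 and rose by 0.68 with cystamine there (SE 0.12, adjusted p = 0.00723). Dusp4 stood at −0.66 with Boc-DON in Q111 (adjusted p = 0.0689, blocked 0.00485) and rose by 0.62 with cystamine (adjusted p = 0.0477). Prl2c2 in Q7 had a blocked estimate of −1.16 with Boc-DON (blocked adjusted p = 0.027, and 0.0984 without the block) and rose by 2.24 with cystamine. The fall of Slc46a3 with cystamine lost its call without each array but cystamine replicate 2 in Q111 (adjusted p up to 0.131) and without replicate 2 or 3 of either group in Q7 (up to 0.237). With the block, genes past the threshold for both compounds in Q111 numbered 9 in opposite and 2 in the same direction, against 0.86 and 0.504 expected of independent lists, and in Q7 5 and 2, against 0.159 and 0.0718. The opposite genes in both lines were Cdx2, Dusp4, Mmp10 and Slc46a3. The doses differ (50 µM and 250 µM), so the values stand side by side.

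Of the 6 pairs of compounds within a line, ZDON and Boc-DON in Q111 had blocked effects with a correlation across genes of 0.686, against 0.504 simulated from shared controls alone, and a covariance of 0.0221 against 0.0104. In Q7 these were 0.437 against 0.442, and 0.0134 against 0.0104. Boc-DON and cystamine lay below the simulated values, at 0.157 against 0.5 in Q111 and 0.119 against 0.44 in Q7, as did ZDON and cystamine, at 0.318 against 0.501 and 0.14 against 0.497, although the covariance of that pair in Q111 was 0.0113 against 0.0104. Genes are not independent replicates, and no p was computed. With the block both ZDON and Boc-DON in Q111 moved Cacna1a, Cdkn1a, Krtap1-5, Lce1f, Lrp11, Mib2 and Spidr in the same direction. Independent lists would give 0.0643 of these 7, a number that leaves out the shared controls, which alone push a pair of effects to the same sign.

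The difference between the lines was smaller on chip 3 in the untreated, ZDON and cystamine arms, with slopes of 0.624, 0.639 and 0.523 of the mean of chips 1 and 2. A compressed scale of that chip is argued against by the genes that answer cystamine, whose lower slope of the lines was 1.05 of that of the other chips. Mixed or mislabelled control arrays alone would leave the treated arms as they were, but the higher of their ratios was 0.639. Q7 cells or RNA in the Q111 samples of chip 3 may be a cause, since the shares of Q7 needed by 60 genes higher in Q111 (0.575, quartiles 0.46 to 0.711) and 24 genes lower (0.489, quartiles 0.239 to 0.643) differed by 0.086. A uniform shrinkage of the line difference would give like shares, the Q7 arrays moved too on chip 3 (by −0.305 for genes lower and −0.0724 for genes higher in Q111), and a difference in culture or passage stays open, as untested.

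Line genes taken from untreated arrays mostly moved with opposite sign under each compound in Q111, which could be read as a return towards Q7. Shared control arrays alone gave shares of up to 72.1% for ZDON and 72.3% for cystamine, which cover the 70.6% and 68.0% seen, and up to 72.5% for Boc-DON, where the 62.7% seen lay below the simulated range, although simulations that held the chip differences reached down to 61.2%. A move towards Q7 cannot be told apart from no move, because with single arrays left out the shares from separate arms ranged from 40.4% to 62.3%, 37.5% to 60.5% and 36.8% to 65.7%, and median scaling gave 68.3% with cystamine. The 10 splits decide nothing, since with measured shares near 50 almost any split lies as far off (9 or all 10). Since the line genes came from arms given other compounds, genes that those compounds return to Q7 levels could be missed.

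Bag3 was higher in Q111 in every arm, by a measured 3.72 untreated, 3.82 with ZDON, 3.43 with Boc-DON and 3.69 with cystamine, sizes that depend on the background, since Q7 means lay between 6.228 and 6.517 and the median probe at 6.87. A raised heat shock response would lift the other heat shock genes with it, but the upper quartile of the 17 others was 0.065, their median −0.0915, and 0 were higher and 1 lower past the test. A sequence difference under the probe in one line may account for it and cannot be told apart from a difference in transcript level, since the array has 0 other Bag3 probes. A difference of the Bag3 gene or its regulation between the lines stays open, as untested.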
